A study of Mus musculus with 6 samples.

How the data were processed

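Total RNA of 6 mouse lung samples was labelled with biotin and hybridised to the Affymetrix Mouse Genome 430 2.0 array, named in the probe table. RNA was extracted with TRIzol and a column, and its quality was assessed on a Bioanalyzer, per the labels' protocols. The values deposited by the authors are linear intensity per probe set, already summarised and scaled; the software and method are not given in the sources used here. From the values, array medians lie between 95.7 and 99.5, a spread of 4.00%, the maximum is 17030, and each array holds 761 to 907 values at exactly 1, which marks a floor. Between 17.1% and 19.0% of values per array lie below 16. No detection calls were used here. Values near the top of the range can be compressed, and folds of genes near the floor are understated by the offset.

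The array has 45101 probe sets, of which 64 are controls. The probe table, taken from the platform annotation, gives 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Symbols were brought up to date through gene identifiers against a RefSeq gene table of the assembly GRCm38.p6, which matched 34741 of those with 1 symbol. Probe sets with several symbols or none were not named, so genes absent from the table, Pten and Spp1 among them, were not analysed here. No coordinates are given, since the files name no build. For each of 18193 genes the probe set with the highest mean over the 6 arrays was used; 9010 genes had more than 1.

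Groups were taken from the sample labels, with 3 control lungs and 3 tumours, each from 12-month-old mice. The labels call the controls Cre carriers, and the protocol text calls them wild type. Nothing in the labels states that the samples come from separate animals, and p-values then measure the spread between these samples. No 2 arrays were duplicates: the largest number of equal values above the floor in any pair was 31. Because medians differed by under 10%, no further normalization was applied, and log2(intensity + 16) was used. Fold changes are on this scale. Changes were tested with lmFit and eBayes in limma 3.58.1 (R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 38 lists that had at least 5 measured members. camera with an estimated correlation and fry were run beside it. The sex-linked list was used to look at the balance of the groups and was not tested. Of 558 list entries 522 were measured, and no gene was in more than 1 of the tested lists.

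The lists, the tests and the rule for naming genes were set before the data were examined. The rule named Pten and Smad4; the 10 largest changes each way among genes past the threshold whose groups do not overlap and whose higher group mean exceeds the median of all genes; 16 fixed genes; the 3 passing members with the largest change of each main list and up to 2 of each other list; and, where no member of a list passed, the 2 with the largest change. Other genes are named only as sex-linked or quality measures or as members of 2 cartilage and Schwann cell lists written later, before their values were looked up, save for Egr2 and Erbb3, which other lists hold.

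Alternatives were quantile normalization, centring on the median, the mean of a gene's probe sets, the probe set with the largest interquartile range, each probe set on its own, leaving out the dimmest 40% of genes, leaving out probe sets that can cross-hybridise (suffix _x_at or _s_at), eBayes with trend and robust options, array weights, offsets of 1 and 64, the replicate number as a block, a test against a log2 change of 0.5, and leaving out each array in turn. Sex as a covariate, read from Xist and Y-linked genes, was added after seeing the data. No label states that equal replicate numbers pair the samples.

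The procedure was tested on simulated data for the 18193 genes with the control means and limma's moderated spreads, 3 arrays against 3, and 200 changed genes in each of 5 runs, drawn from genes above the median level. It recovered 13.3% of changes of 0.5 on the log2 scale, 86.2% of those of 1 and 97.3% of those of 2, and 7.01% of its calls were false. A list shifted by 0.5 was called, and 0 other lists were. Genes were drawn independently in the simulation, so it does not show how camera performs where genes of a list move together.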

Results

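Gene expression was measured on 6 Affymetrix mouse arrays, 1 per lung sample. The 3 control samples were lungs labelled as normal, from mice whose genotype is given as a Cre recombinase in the club cell secretory protein locus. The protocol text calls these mice wild type. The 3 tumour samples were macrodissected from mice in which that Cre deleted Pten, a lipid phosphatase that restrains PI3K signalling, and Smad4, the shared transducer of TGF-beta and BMP signals. All mice were 12 months old and of mixed C57BL/6 background. Throughout, "tumour" stands for the 3 arrays labelled as double-knockout tumour. Genotype and tissue differ together between the groups, because tumour was compared with normal lung. List members not counted below as risen or fallen did not pass the test. The arrays had median intensities between 95.7 and 99.5. Pairwise correlations of gene values, taken across genes, which are not independent replicates, were 0.982 to 0.991 among controls, 0.984 to 0.988 among tumours and 0.943 to 0.978 between the groups. The number of arrays limits the precision of every value.

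Smad4 transcript was present in both groups. In each of its probe sets every tumour array read above every control array, though no difference passed the threshold in the main fit. The probe set with the largest difference read 2631 ± 138 (SD, n = 3) in controls and 3425 ± 183 (SD, n = 3) in tumours, a log2 difference of 0.38 ± 0.09 (SE) with a limma adjusted p of 0.0522. The other probe sets read 2111 ± 80.2 against 2487 ± 123 (adjusted p = 0.154) and 2819 ± 137 against 3303 ± 364 (adjusted p = 0.268). No Smad4 probe set was lower in tumours, in any array. The first of these differences passed the threshold, as higher in tumours, with array weights (adjusted p = 0.0379), with a trended robust variance (0.0140) and with an offset of 64 (0.0233), and had an adjusted p of 0.370 with sex as a covariate. The position of these probes relative to the deleted exons is not given in the sources used here, and a probe outside the deleted part checks nothing, so Smad4 could not be used to check the labels. Pten is not named by the probe table used here and was not analysed.

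The first question was how the transcripts of double-knockout tumours differ from those of control lung. The basal keratins Krt15 and Krt14 were among the 10 most raised genes. Krt15, a basal cell keratin, went from an intensity of 18.6 ± 9.34 (SD, n = 3) in controls to 2045 ± 1115 (SD, n = 3) in tumours, 55.7-fold on the offset scale (log2 5.80 ± 0.39, SE, adjusted p = 0.00299). The chemokines Cxcl3 and Ccl3 and the fibrinogen chains Fga and Fgg were among the 10 most lowered. The neutrophil chemokine Cxcl3 fell from 2641 ± 1519 to 251 ± 241, 11.2-fold (log2 -3.48 ± 0.78, SE, adjusted p = 0.0338). Of 18193 genes, 2768 changed at an adjusted p under 0.05, of which 1683 rose and 1085 fell. At least 2-fold changes were seen in 1020 genes, 738 higher and 282 lower. In 6793 genes, 37.3% of all, the groups did not overlap, where chance gives 10% for 3 samples against 3. The count of changed genes was 1011, 1269 and 854 without control replicates 1, 2 and 3, and 1181 and 1225 without tumour replicates 1 and 3. In the same order 736, 924, 628, 816 and 854 rose and 275, 345, 226, 365 and 371 fell. Changes of at least 2-fold numbered 630, 515, 666 and 622 without control replicates 1 and 3 and tumour replicates 1 and 3. Without tumour replicate 2 the count rose to 3299 changed genes, 1315 of them over 2-fold. Each of these fits had fewer arrays, and how far that alone accounts for the lower counts was not tested.

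The other genes among the 10 most raised were the sulfotransferase Sult1c1 (log2 change 5.77 ± 0.19, SE), the epidermal lipoxygenase Alox12e (5.55 ± 0.30), Wfdc18 (5.06 ± 0.72), the mucin-like Glycam1 (4.61 ± 0.28), the basal keratin Krt14 (4.55 ± 0.32), the calmodulin-like Calml3 (4.55 ± 0.25), Agr2, a protein disulfide isomerase needed for mucin folding (4.44 ± 0.52), Prp2 (4.38 ± 0.52) and the glycoprotein Gp2 (4.38 ± 0.75). Sult1c1 rose from 6.63 ± 4.10 to 1220 ± 227. Its groups do not overlap, which the rule required of every gene among the 10 most raised or most lowered. The order of the most raised genes rests on the offset, and with an offset of 1 Sult1c1 (7.45), Alox12e (6.85) and Glycam1 (6.78) lay above Krt15 (6.68). After Cxcl3, the 10 most lowered genes were the oxidised lipoprotein receptor Olr1 (-3.33 ± 0.61), the zinc transporter Slc39a2 (-3.20 ± 0.41), the macrophage chemokine Ccl3 (-3.17 ± 0.30), the fibrinogen chains Fga (-3.13 ± 0.63) and Fgg (-3.01 ± 0.54), Stra6l (-2.94 ± 0.41), the glutamate transporter Slc1a2 (-2.81 ± 0.36), the cation channel Mcoln3 (-2.76 ± 0.58) and the cytokine Il1a (-2.69 ± 0.26). Adjusted p lay between 8.05e-04 (Sult1c1) and 0.0338 (Cxcl3) over these 20 genes. Gp2 passed the threshold neither without tumour replicate 1 (adjusted p = 0.0620) nor without tumour replicate 3 (0.0589), and Olr1 did not without any 1 control replicate (up to 0.0755). Fga (up to 0.0881) and Fgg (up to 0.0669) did not pass without control replicates 1 or 3 or tumour replicates 1 or 3, Cxcl3 (up to 0.108) without control replicates 2 or 3 or tumour replicates 1 or 3, and Mcoln3 (up to 0.0792) without any 1 array other than tumour replicate 1.

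**Figure D1:**
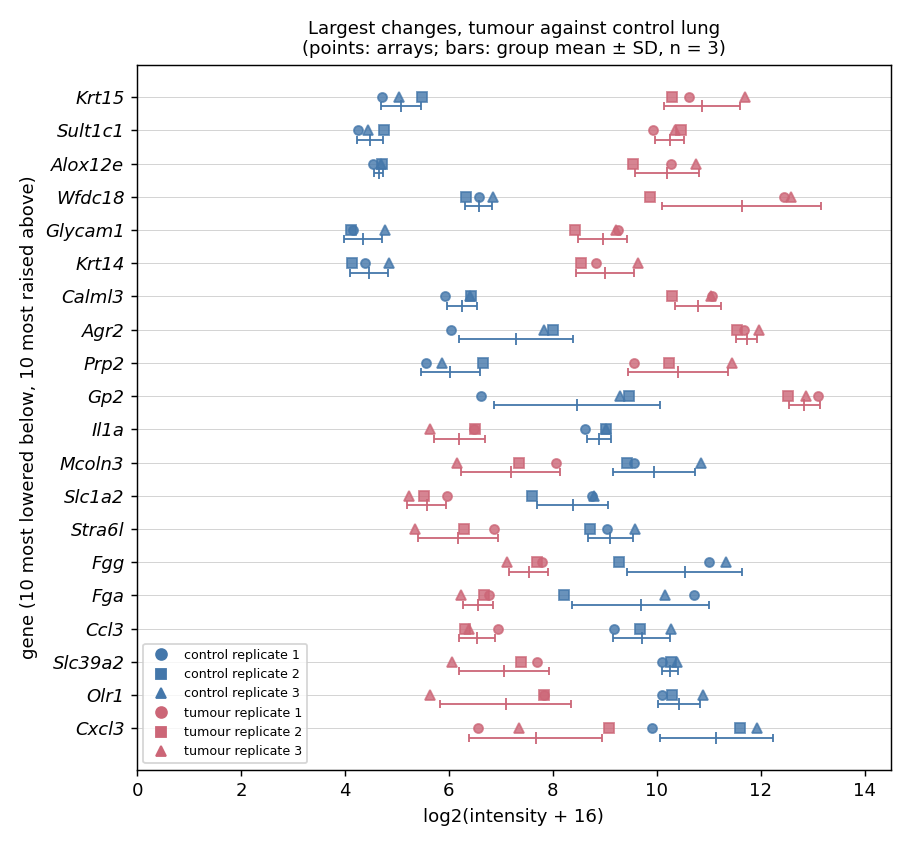
Intensities of the 10 most raised and 10 most lowered genes, as log2(intensity + 16) on the horizontal axis and genes on the vertical axis, with 1 point per array (blue, 3 control lungs; red, 3 tumours) and bars for the mean ± SD of each group of 3. In every gene shown the groups do not overlap, by the rule that chose them; with the offset of 16, Krt15 rises by log2 5.80 and Cxcl3 falls by log2 -3.48.

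The groups also differed in sex and in ribosomal RNA signal. Xist, the X-inactivation transcript of female cells, read 6786 and 6917 in control replicates 1 and 3, 69.8 in control replicate 2, and 237, 175 and 64.1 in tumour replicates 1, 2 and 3. The Y-linked Eif2s3y read 20.6 and 13.7 in control replicates 1 and 3 and 1796 in control replicate 2, against 1567, 1908 and 1640 in the tumours. With sex as a covariate, a fit in which control replicate 2 alone carries the comparison, 1 gene passed limma's adjusted threshold, Sult1c1 (log2 5.49 ± 0.24, SE, adjusted p = 0.0378), and 3188 genes had an unadjusted p under 0.05, 1898 higher and 1290 lower. For each of the 2768 changed genes, the log2 change in that fit was divided by the one without the covariate, and the median ratio was 0.938. Control replicate 2 enters both fits, so this ratio says little about sex. None of these genes could change direction, because the groups do not overlap in any of them. Their unchanged direction therefore says nothing about sex. The 18S ribosomal RNA control probe sets averaged 6381 ± 778 (SD, n = 3) in controls and 1700 ± 504 (SD, n = 3) in tumours, 3.75-fold lower in tumours (2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The 3′ to 5′ ratios of Actb (1.66 ± 0.0291 and 1.70 ± 0.119) and Gapdh (1.37 ± 0.0163 and 1.37 ± 0.167) differed by less than the spread among tumours. The poly-A spike-ins, added to the RNA before labelling, read higher in every tumour than in every control, at a mean log2 intensity of 7.30 ± 0.11 (SD, n = 3) against 7.07 ± 0.13 (exact permutation p = 0.1).

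Many epithelial genes rose in tumours. Of 19 general epithelial genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), among them the tight junction gene Cldn4 (114 ± 26.4 to 539 ± 183, 4.17-fold, log2 2.06 ± 0.26), the stem cell surface protein gene Prom1 (1.70 ± 0.25) and the keratin Krt19 (1.70 ± 0.17). The E-cadherin gene Cdh1 rose by a smaller amount (6061 ± 410.3 to 7890 ± 85.6, log2 0.38 ± 0.08, adjusted p = 0.0307). Of 23 squamous and basal genes, 10 rose and 0 fell (12 and 1 adjusted over the list alone), led by Krt15, Krt14 and Calml3. The basal cell transcription factor Trp63 rose 6.45-fold (35.7 ± 9.15 to 332 ± 142) and the basal keratin Krt5 rose 14.4-fold (32.3 ± 7.62 to 758 ± 450.1). Of 18 mucous and gastrointestinal-type genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with Agr2, the antibacterial lectin Reg3g (8.16-fold, log2 3.03 ± 0.48) and the airway mucin Muc5b (4.96-fold, log2 2.31 ± 0.40). These genes also varied together among control replicates 1, 2 and 3: Agr2 read 49.6, 240 and 213, Reg3g 760, 3094 and 2024, and Muc5b 592, 1841 and 1383. Bpifa1, Gp2 and Ltf were likewise lowest in control replicate 1, and the cause was not tested. camera with a preset correlation called all 3 lists as higher, with adjusted p of 8.90e-12 (general epithelium), 2.56e-06 (squamous and basal) and 0.0143 (mucous), and none held with an estimated correlation (adjusted p = 0.393 for each). The squamous and basal count stayed between 9 and 11 when any 1 array was left out, the general epithelial count fell to 11 without control replicate 3, and the mucous count fell to 5, 2, 2 and 4 without control replicates 1 and 3 and tumour replicates 1 and 3. Cdh1 lost its call without any 1 array other than control replicate 2 (adjusted p of up to 0.104), Prom1 without control replicate 3 (0.0508), Reg3g without control replicate 3 or tumour replicate 1 (up to 0.0511), and Muc5b without control replicate 3 or tumour replicate 1 or 3 (up to 0.0620).

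Most ciliated cell genes and some club cell genes were also higher. Of 17 ciliated cell genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone), by a list median of 1.34 on the log2 scale, including the axonemal dynein Dnah9 (338 ± 64.9 to 1233 ± 354, log2 1.79 ± 0.25), the cadherin Cdhr3 (1.70 ± 0.23) and the radial spoke gene Rsph1 (1.60 ± 0.21). Foxj1, the regulator of motile cilia, rose 2.13-fold (adjusted p = 0.0141), and lost its call without control replicate 1, control replicate 3 or tumour replicate 1 (adjusted p of up to 0.0558). camera called the list as higher (adjusted p = 1.11e-08; adjusted p = 0.440 with an estimated correlation). Of 14 club cell genes, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with the secreted airway protein Bpifa1 (3410 ± 2044 to 14397 ± 369, log2 2.30 ± 0.50), Upk3a (1.44 ± 0.14) and the claudin Cldn10 (1.35 ± 0.18). camera called this list as higher (adjusted p = 0.00361; adjusted p = 0.397 with an estimated correlation). The club cell marker Scgb1a1 read 14744 ± 489 in controls and 15140 ± 576 in tumours (adjusted p = 0.787), close to the highest value on any array, 17030, as did Bpifa1 and Reg3g in tumours. The ciliated count fell to 8 without control replicate 3, and the club cell count fell to 3 without control replicate 1 and to 2 without control replicate 3, tumour replicate 1 or tumour replicate 3. Bpifa1 lost its call without control replicate 3 or any 1 tumour array (adjusted p of up to 0.0920).

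Many endothelial and resident fibroblast genes were lower in tumours, while few alveolar genes passed the test. Of 20 endothelial genes, 12 fell and 0 rose (17 and 0 adjusted over the list alone), among them Sox17 (1634 ± 50.7 to 608 ± 259.8, log2 -1.49 ± 0.30), the angiopoietin receptor Tek (-1.43 ± 0.27), the claudin Cldn5 (-1.33 ± 0.28) and Pecam1 (-0.98 ± 0.17). Of 13 resident lung fibroblast genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone), including the matrix gene Mfap4 (3485 ± 221 to 1023 ± 244, log2 -1.78 ± 0.17) and Fgfr4 (-1.54 ± 0.23). Of 14 alveolar type 1 genes, 4 fell and 0 rose (12 fell and 1 rose adjusted over the list alone), with the sodium channel subunit Scnn1g (-1.48 ± 0.38, adjusted p = 0.0499), Igfbp2 (-1.12 ± 0.29) and the caveolin Cav1 (-0.63 ± 0.14). None of 14 alveolar type 2 genes passed limma's threshold (0 adjusted over the list alone; 7 fell without tumour replicate 2), and 13 of them had a negative change, the largest being Etv5 (-1.09 ± 0.44, adjusted p = 0.150) and Lpcat1 (-0.84 ± 0.50, adjusted p = 0.311). The surfactant gene Sftpc read 11930 ± 301 and 11722 ± 329 (adjusted p = 0.855), and the lung transcription factor Nkx2-1 read 195 ± 22.2 and 139.9 ± 21.7 (adjusted p = 0.0835). Sftpc has 2 probe sets, and the one with the largest interquartile range gave a positive change that did not pass either. Scnn1g lost its call without any 1 control array or tumour replicate 1 (adjusted p of up to 0.135), with quantile normalization (0.0503), with the mean of each gene's probe sets (0.0508), with each probe set on its own (0.0616) and with an offset of 1 (0.0740), and Igfbp2 (up to 0.134) and Cav1 (up to 0.102) without any 1 array other than tumour replicate 2. Scnn1g has 1 probe set, so the 2 probe set settings acted on its adjusted p only through other features. Pecam1 lost its call without any 1 control array (up to 0.0626).

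camera called these lists as lower, with adjusted p of 1.11e-08 (endothelium), 2.96e-07 (resident fibroblast), 3.04e-04 (alveolar type 1) and 0.0128 (alveolar type 2), and with an estimated correlation the adjusted p was 0.440, 0.393, 0.505 and 0.676. Tumour replicate 2 kept the highest alveolar signal of the tumours, with a mean log2 value over the alveolar type 2 list of 12.28 against 11.64 and 11.14 in tumour replicates 1 and 3 and 12.11 to 12.18 in controls. This was not particular to alveolar genes, since the same array was the tumour closest to the controls in most other called lists. The mucous, club cell, macrophage and NRF2 lists were exceptions. Without tumour replicate 2, 10 alveolar type 1 genes fell, and the count was 0 without control replicate 1, 2 or 3 or tumour replicate 1 and 1 without tumour replicate 3. The alveolar type 2 call ended without tumour replicate 3 (adjusted p = 0.0839). The endothelial count fell to 1 or 2 without any 1 control replicate or tumour replicate 1, and the resident fibroblast count to 2, 3 or 4 without any 1 array other than tumour replicate 2. Sox17, Tek and Cldn5 lost their calls without any 1 control array or tumour replicate 1, with adjusted p of up to 0.0944.

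Some macrophage genes were lower in tumours. Of 9 alveolar macrophage genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with a list median of -1.71, including Krt79 (1196 ± 244 to 179 ± 61.4, log2 -2.67 ± 0.26) and the proton pump subunit Atp6v0d2 (5280 ± 769 to 1019 ± 550.3, log2 -2.54 ± 0.47). camera called the list as lower (adjusted p = 5.73e-05; adjusted p = 0.393 with an estimated correlation). Of 15 general macrophage genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone), led by Gpnmb (-2.26 ± 0.42), the lipid receptor Trem2 (-1.96 ± 0.30) and the lysosomal protein Cd68 (3533 ± 853 to 976 ± 258, log2 -1.85 ± 0.26). The call on that list (adjusted p = 0.0276; adjusted p = 0.621 with an estimated correlation) ended without control replicate 1 (0.110), without tumour replicate 2 (0.126), with the replicate block (0.104), with the dim genes left out (0.0523), with cross-hybridising probe sets left out (0.0792) and with sex as a covariate (0.5003). Its count of falling genes was 2 or 3 without any 1 array other than tumour replicate 2. Trem2 lost its call with cross-hybridising probe sets left out, where its other probe set gave a log2 change of -0.02 (adjusted p = 0.920). Gpnmb lost its call without any 1 control array or tumour replicate 3 (adjusted p of up to 0.0731), and Atp6v0d2 without any 1 control array (up to 0.0763). Of 14 T and NK cell genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone), the NK receptor Ncr1 (-0.92 ± 0.18) and Cd2 (-0.60 ± 0.14). The call on this list (adjusted p = 0.0172; adjusted p = 0.505 with an estimated correlation) ended without control replicate 1 (0.0930), without control replicate 2 (0.0514) and with the dim genes left out (0.162). Ncr1 lost its call without control replicate 1 or 2 or tumour replicate 1 or 3 (up to 0.0851), and Cd2 without any 1 array other than tumour replicate 2 (up to 0.124). The count of 2 fell to 1 without control replicate 3 and to 0 without control replicate 1, control replicate 2, tumour replicate 1 or tumour replicate 3.

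Genes of the list of neutrophil genes and chemokines moved in both directions. Of 15 neutrophil and chemokine genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone). The iron-binding granule and secretory protein gene Ltf rose (1404 ± 1033 to 9738 ± 325, log2 3.29 ± 0.81, adjusted p = 0.0434), and the chemokines Cxcl3 and Cxcl2 (571 ± 168 to 90.8 ± 17.5, log2 -2.43 ± 0.24) fell. camera did not call the list (adjusted p = 0.991), whose median (0.24) and mean (-0.04) differ in sign. Ltf lost its call without any 1 array other than control replicate 1 (adjusted p of up to 0.122), after which the list had 0 risen genes, save that 1 rose without tumour replicate 2. Of 17 matrix protease and inhibitor genes, 4 rose and 1 fell (5 and 4 adjusted over the list alone), with the stromelysin Mmp3 (278 ± 63.2 to 1282 ± 466, log2 2.10 ± 0.29), Adam8 (2.02 ± 0.26) and the aggrecanase Adamts4 (1.60 ± 0.12) the most raised. No gene of it fell without any 1 control array, and 2 fell without tumour replicate 1 or 2. This list was not called (adjusted p = 0.991), and its median (-0.12) and mean (0.18) differ in sign.

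The next comparisons concerned the pathways of the deleted genes. A list of ErbB receptors, their ligands and Elf3, an epithelial ETS factor, was written because the study of these samples is known for its interest in them, so its count is not independent evidence. Of its 15 genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Elf3 rose from 506 ± 42.0 to 1993 ± 494 (3.77-fold, log2 1.91 ± 0.20, adjusted p = 0.00570) and the receptor Erbb2 from 167 ± 18.9 to 308 ± 28.3 (1.77-fold, log2 0.82 ± 0.11, adjusted p = 0.0103). Both calls held without any 1 array (adjusted p of up to 0.0330 and 0.0410). The adaptor Grb7 rose by less (log2 0.35 ± 0.08, adjusted p = 0.0392, up to 0.117 without 1 array), and lost its call with an offset of 1, with each gene's probe set of largest interquartile range, with each probe set on its own, with arrays centred on their median and without any 1 array other than tumour replicate 2. Grb7 has 1 probe set, so the probe set settings acted on its adjusted p only through other features. Erbb3 read 877 ± 43.1 and 962 ± 101 (adjusted p = 0.465). camera did not call the list (adjusted p = 0.308).

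TGF-beta and BMP response genes moved in both directions, with 2 of 17 raised and 3 lowered (3 and 6 adjusted over the list alone). The matrix protein Tgfbi rose (1889 ± 91.9 to 2948 ± 206, log2 0.64 ± 0.09), and Tgfb1 (-0.98 ± 0.18) and the BMP target Id1 (1578 ± 174 to 830.4 ± 254, log2 -0.95 ± 0.23) fell. The Tgfbi call held without any 1 array (adjusted p of up to 0.0457), and that of Tgfb1 ended without control replicate 1 or 3 (up to 0.0590) and that of Id1 without any 1 array other than tumour replicate 2 (up to 0.124). The count of falling genes was 0 without control replicate 1 or 3, 1 without control replicate 2 or tumour replicate 1 and 5 without tumour replicate 2. Of 16 FOXO targets that PI3K-AKT signalling represses, 1 rose (Sesn3, log2 0.65 ± 0.13) and 1 fell (Ccng2, log2 -0.60 ± 0.09), with 2 and 2 adjusted over the list alone. Sesn3 lost its call without any 1 control array or tumour replicate 3 (adjusted p of up to 0.0846) and Ccng2 without control replicate 3 (0.0532), while 3 rose and 2 fell without tumour replicate 2. camera called neither list (adjusted p = 0.308 and 0.377).

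Proliferation genes gave no list call in these tumours. Of 25 such genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone), the mitotic checkpoint kinase Bub1b (153 ± 26.9 to 78.4 ± 16.9, log2 -0.84 ± 0.17, adjusted p = 0.0265), which lost its call without control replicate 2 or 3 or tumour replicate 2 or 3 (up to 0.0877) and with cross-hybridising probe sets left out (0.0613); 2 genes fell without tumour replicate 1 and 0 without control replicate 2, control replicate 3 or tumour replicate 3. The cell cycle marker Mki67 read 406 ± 87.5 in controls and 337 ± 24.3 in tumours (adjusted p = 0.405). camera gave the list an adjusted p of 0.377 and a median log2 change of -0.03. Fibrillar matrix genes had a median of 0.57, and 1 of 17 rose (0 adjusted over the list alone), the thrombospondin Thbs2 (65.4 ± 4.86 to 194 ± 99.7, log2 1.26 ± 0.32, adjusted p = 0.0459), which lost its call without any 1 control array or tumour replicate 2 (up to 0.131), with each probe set on its own (0.0570) and with offsets of 1 (0.0592) and 64 (0.0552). The count was 0 without those arrays, 3 without tumour replicate 1 and 2 without tumour replicate 3. The collagen gene Col1a1 read 669 ± 229 and 1830 ± 747 (adjusted p = 0.0560). This list was not called (adjusted p = 0.121), except without tumour replicate 1 (0.00453) and with the replicate block (0.0165), where 3 genes rose. The mesenchymal filament gene Vim read 12511 ± 439 and 10036 ± 719 (adjusted p = 0.0572). Among 10 genes of epithelial to mesenchymal transition, 2 rose and 2 fell (4 and 3 adjusted over the list alone), with Twist1 at a log2 change of 0.95 ± 0.15, from a low level of 11.0 ± 2.63, and Zeb2 at -0.74 ± 0.15. Twist1 lost its call without control replicate 3 (0.0558) and Zeb2 without any 1 control array or tumour replicate 1 (up to 0.0886). The risen count was 0 without control replicate 3 and 1 without any other array but tumour replicate 2, and the fallen count 0 without any 1 control array or tumour replicate 1 and 1 without tumour replicate 3. That list was not called (adjusted p = 0.927), and its median (-0.04) and mean (0.06) differ in sign.

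Some interferon, NRF2 and hypoxia genes were higher in tumours. Of 12 interferon response genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), among them the oligoadenylate synthetase-like Oasl2 (264 ± 12.4 to 1028 ± 361, log2 1.83 ± 0.27) and Ifit1 (395 ± 12.4 to 1205 ± 219, log2 1.56 ± 0.14). Of 11 NRF2 targets, 7 rose and 0 fell (8 and 0 adjusted over the list alone), including the glutathione peroxidase Gpx2 (505 ± 135 to 2265 ± 324, log2 2.15 ± 0.20) and the quinone reductase Nqo1 (0.94 ± 0.21). Of 13 hypoxia and glycolysis genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), including the prolyl hydroxylase Egln3 (66.5 ± 6.41 to 235 ± 66.0, log2 1.57 ± 0.21) and the glucose transporter Slc2a1 (0.69 ± 0.17). camera called all 3 as higher (adjusted p = 0.00790, 0.00361 and 0.00561), and with an estimated correlation the adjusted p was 0.440, 0.393 and 0.393. The NRF2 count fell to 2, 3 or 4 and the hypoxia count to 1 without any 1 array other than tumour replicate 2, and the interferon count fell no lower than 4. Slc2a1 (adjusted p of up to 0.132) and Nqo1 (up to 0.109) each lost their call in 5 fits, Slc2a1 keeping it without tumour replicate 2 and Nqo1 without tumour replicate 3. The fallen interferon gene passed only with all arrays or without tumour replicate 1.

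Genes of other tissues were examined as possible content of the dissected samples. Of 12 cardiac muscle genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a list median of 1.33. The atrial peptide gene Nppa rose from 194 ± 108 to 2386 ± 1365 (10.5-fold, log2 3.40 ± 0.61), and the oxygen store Mb from 655 ± 148 to 2235 ± 77.4 (log2 1.77 ± 0.16). camera called the list as higher (adjusted p = 8.44e-08; adjusted p = 0.422 with an estimated correlation). The count fell to 7 without control replicate 1 or 3, and Nppa lost its call without control replicate 1 or 3 or tumour replicate 1 or 3 (adjusted p of up to 0.0708). Of 12 smooth muscle and pericyte genes, 1 rose and 2 fell (3 and 2 adjusted over the list alone), with Rgs5 up (221 ± 13.1 to 1909 ± 577, log2 2.98 ± 0.20) and Higd1b down (-1.11 ± 0.18). Higd1b lost its call without control replicate 2 or 3 or tumour replicate 1 (up to 0.0600). The fallen count was 1 without any 1 control array or tumour replicate 1, and the risen count 2 without tumour replicate 1. That list was not called (adjusted p = 0.121), except without control replicate 2 (0.0453), without tumour replicate 1 (0.0392), with the replicate block (0.0483) and with cross-hybridising probe sets left out (0.0402). Of 10 skeletal muscle genes, 1 rose (Ckm, log2 1.19 ± 0.17; 1 adjusted over the list alone), and of 8 adipocyte genes, 1 rose (Cidea, log2 1.81 ± 0.28; 2 adjusted over the list alone). Neither list was called (adjusted p = 0.368 and 0.205), except for the adipocyte list without tumour replicate 1 (0.0485), where 2 of its genes rose. In turn, 1 skeletal muscle gene fell without tumour replicate 2. Of 8 mesothelial genes, 3 rose and 2 fell (3 and 4 adjusted over the list alone), with the cell surface proteins Muc16 (116 ± 18.4 to 1235 ± 354, log2 3.22 ± 0.21) and Msln (329 ± 98.8 to 2585 ± 837, log2 2.90 ± 0.33) raised. The fallen count was 0 without control replicate 1 or 3 or tumour replicate 1 or 3 and 4 without tumour replicate 2. That list was not called (adjusted p = 0.928), and its median (-0.69) and mean (0.17) differ in sign.

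**Figure D2:**
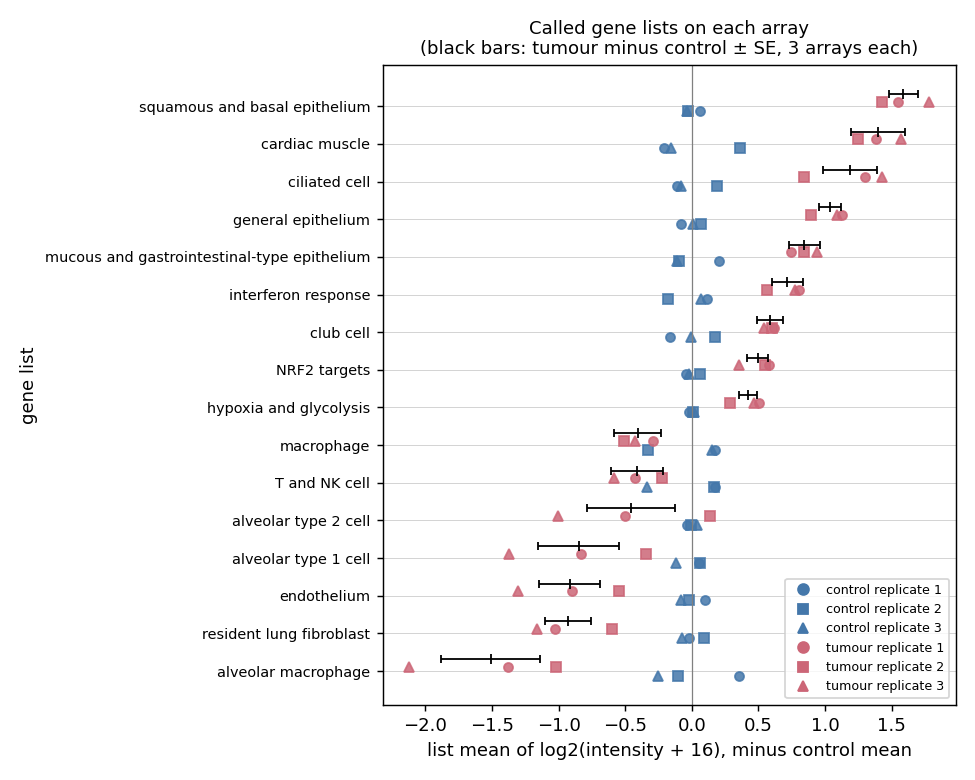
Mean log2(intensity + 16) of the genes of each of the 16 called lists on every array, minus the mean of the 3 controls, on the horizontal axis, with the lists on the vertical axis; points are arrays (blue, control; red, tumour) and black bars give the tumour minus control difference ± SE. The squamous and basal list has the largest rise (1.59 ± 0.11) and the alveolar macrophage list the largest fall (-1.51 ± 0.37). Of the tumours, replicate 2 lies closest to the controls in the alveolar lists and in most other lists shown. The mucous, club cell, macrophage and NRF2 lists are exceptions.

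Across the comparison, camera called 16 of 38 lists, 9 higher and 7 lower. No call held with camera's estimated correlation, where 2 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.393. fry, which tests whether a list's genes move one way on balance without comparing them with other genes, called 14 lists, of which 12 were among the 16. With sex as a covariate, control replicate 2 was the only control left to compare, and all 16 medians kept their sign. Members that passed in the main fit could not change sign, because their groups do not overlap. The kept signs therefore say little about sex, which stays open for every list. Of 111 named genes 95 passed the threshold, and 52 of these passed it in each of the 6 fits that left out 1 array. Calls also ended with an offset of 1 for Cxcl3, Igfbp2, Id1, Ltf, Cd2, Jun, Slc2a1, Notch4 and Nrarp, with each probe set on its own for these except Cxcl3 and Nrarp, and with the mean of probe sets for Syp and Slc2a1.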

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

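The test that relates ciliated cell genes to cartilage and nerve genes was set before its result was seen, as were the counts over other splits of the arrays; the other tests in this part were chosen after the results they bear on. For the tests of sex, alveolar share, dilution and heart-type muscle, the bounds were also changed, to stricter ones, after a first run's verdicts had been seen, and the test of even dilution was replaced.

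Probe sets without a single gene name lie outside the comparison of named genes, and some of them changed as well. Of 10092 such probe sets, 93 rose and 49 fell at least 2-fold with an adjusted p under 0.05 in limma over 45037 probe sets. The most raised were a probe set at 7.38 ± 2.78 to 158 ± 59.2 (SD, n = 3), log2 2.85 ± 0.24 (SE), and another at 85.2 ± 9.08 to 545 ± 226, log2 2.38 ± 0.32. The most lowered were at 339 ± 121 to 36.7 ± 16.2, log2 -2.75 ± 0.29, and at 337 ± 28.6 to 51.5 ± 20.7, log2 -2.43 ± 0.23.

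Cardiac muscle genes were higher in tumours, by a mean of 1.40 ± 0.20 (SE) on the log2 scale. Sex stays open, since the tumours exceeded control replicate 2, the only control of their sex pattern, by 1.04 ± 0.155 (SE with a spread taken from the other groups), and 1 array excludes nothing. More heart-type muscle in the dissected tissue is a candidate explanation that stays open too. The genes moved together within groups, with an estimated correlation of 0.644, but so did those of the ciliated (0.737), alveolar type 2 (0.733) and endothelial (0.641) lists. Induction of these genes by loss of Pten and Smad4 was not tested and stays open.

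Ciliated cell genes were higher in tumours, by a mean of 1.19 ± 0.20 (SE). A lower share of alveolar tissue would raise all other cell types alike. The ciliated list exceeded the mean of the T and NK cell, B and plasma cell, and smooth muscle lists by 1.04 ± 0.165 (SE, lower end of the 95% interval 0.583). In that order, these lists shifted by -0.41 ± 0.20, 0.37 ± 0.26 and 0.48 ± 0.16 (SE). Shifts in both directions give no common baseline, so the test does not decide how far a lower alveolar share contributes. Sex stays open, since the shift of 0.9991 ± 0.291 rests on control replicate 2 alone, with a spread taken from the other groups. Cartilage-bearing central airway in the tumour samples stays open: the shift of 1.86 over the 3 cartilage genes above an intensity of 100 in either group and that of 0.40 over 8 Schwann cell genes, under the 0.5 set beforehand for both lists, rest partly on that filter, which Comp, S100b and Ncam1 met through their tumour values alone. Ciliated differentiation of the tumour cells themselves was not tested.

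Alveolar macrophage genes were lower in tumours, by a mean of -1.51 ± 0.37 (SE). Even dilution of all lung cell types by tumour tissue would lower them alike. The T and NK cell, B and plasma cell, and smooth muscle lists together lay above the endothelial and resident fibroblast lists by 1.07 ± 0.242 (SE, 95% interval 0.399 to 1.74). Of these, the T and NK cell list itself fell (-0.41 ± 0.20), and the B and plasma cell (0.37 ± 0.26) and smooth muscle (0.48 ± 0.16) lists were not called. Tumour tissue may also hold such cells of its own, so the test does not decide and dilution stays open. A loss along with the rest of the alveolar tissue stays open: the list's shift differed from the mean of the endothelial and resident fibroblast lists by -0.586 ± 0.220, with a 95% interval (-1.20 to 0.0238) that reaches 0. Sex stays open as well, since the shift from control replicate 2 alone was -1.41 ± 0.603 (95% interval -3.32 to 0.512). A response of macrophages to the deletions was not tested.

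Other splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 2768 changed genes, 1020 of them over 2-fold, and 16 called lists. The other 9 of the 10 splits gave at most 0, 0 and 12, so 1 split, the real one, reached each real value. Lists were thus called by camera at its preset correlation in splits that mix tumours and controls.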

How the results depend on the processing

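Sex as a covariate was the 1 alternative chosen after seeing the data. Quantile normalization, centring, the choice or mean of probe sets, the dim and cross-hybridisation filters, trend and robust options, array weights and offsets of 1 and 64 kept the counts of changed genes, changes over 2-fold and called lists within 1.5 times, except that each probe set on its own gave 1628 for changed genes, lower, with more features tested. A test against a log2 change of 0.5 gave 290 genes, 256 higher and 34 lower, a stricter test by construction. Sex as a covariate gave 1 changed gene, higher and over 2-fold, and 0 lower, with 1 control left to compare. camera with an estimated correlation called 0 lists, and fry 14.

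The replicate block gave 1042 changed genes (712 higher, 330 lower) and 646 changed genes over 2-fold. Deviations of same-numbered arrays correlated, across genes, at -0.12, -0.10 and 0.02, which gives no sign of pairing. Pairing is not excluded, since sex among controls and alveolar signal among tumours can also shape these deviations. The block left 61 of 95 named calls past the threshold.

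Without each array in turn, changed genes ranged from 854 to 3299, higher genes from 628 to 1899, lower genes from 226 to 1400, changes over 2-fold from 515 to 1315, and called lists from 14 to 19. The 95 named genes that passed could not change sign in these fits, because their groups do not overlap. Sftpc reversed with the mean of its probe sets (0.24), with the probe set of largest interquartile range (0.50) and with sex as a covariate (0.00537), and Ighm without cross-hybridising probe sets (-0.34); neither passed the threshold in any of these, and the cause was not tested. Signal over background limits genes near 16, and saturation those near 17030.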

Other observations

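The tests of lists and genes in this part were planned before the data were examined, and that of cartilage and nerve genes was added later, before its result was seen.

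Of 14 lineage transcription factors, 4 rose and 3 fell (5 and 4 adjusted over the list alone): the airway factor Sox2 rose from 1096 ± 275 (SD, n = 3) to 3814 ± 477 (log2 1.80 ± 0.19, SE) and Klf5 from 447 ± 35.5 to 1313 ± 117 (log2 1.52 ± 0.11). camera did not call this list (adjusted p = 0.966), whose median (-0.11) and mean (0.14) differ in sign. Of 16 xenobiotic and retinoid genes, 4 rose and 2 fell (6 and 3 adjusted over the list alone), with the retinol-oxidising Adh7 (116 ± 24.9 to 1083 ± 601, log2 2.94 ± 0.37) and the aldehyde dehydrogenase Aldh3a1 (log2 1.90 ± 0.24) raised, and the list was not called (adjusted p = 0.313). Of 13 WNT targets, 2 rose and 1 fell (3 and 2 adjusted over the list alone), with the WNT antagonist family member Dkk2 (21.2 ± 11.7 to 253 ± 132, log2 2.79 ± 0.39) and Sox9 (log2 1.82 ± 0.20) raised (list adjusted p = 0.788). Of 12 Notch pathway genes, 0 rose and 2 fell (0 and 4 adjusted over the list alone), the endothelial receptor Notch4 (-1.15 ± 0.28) and Nrarp (-0.84 ± 0.19), with a list adjusted p of 0.205 that passed with the mean of probe sets (0.0476). Notch4 (adjusted p of up to 0.127) and Nrarp (up to 0.103) lost their calls without any 1 control array or tumour replicate 1, and Nrarp also without tumour replicate 3. The WNT list had 0 fallen genes without any 1 control array or tumour replicate 1 and 2 without tumour replicate 2, and the xenobiotic list 0 without control replicate 1 or 2 or tumour replicate 3 and 1 without any other array. The lineage list had 1 fallen gene without control replicate 2 or 3 or tumour replicate 1.

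Further lists of cell types and handling were not called. None of 11 B and plasma cell genes (0 adjusted over the list alone) passed limma's threshold, with Ighm at 4467 ± 3761 and 8029 ± 2628 and Cd79a at 99.8 ± 19.1 and 228 ± 112, and the list's adjusted p was 0.295, or 0.0356 without tumour replicate 2. None of 8 MHC class II genes passed (0 adjusted over the list alone), with H2-Ob at a log2 change of 0.34 ± 0.19 and H2-DMa at -0.16 ± 0.11 (list adjusted p = 0.909; median -0.03 and mean 0.01). None of 6 erythroid genes passed (0 adjusted over the list alone), with Alas2 at -1.80 ± 0.60 and Car2 at -1.04 ± 0.41 (list adjusted p = 0.182). Of 10 neuroendocrine genes, 1 fell (Syp, -0.46 ± 0.09; 1 adjusted over the list alone; list adjusted p = 0.313). Of 8 thymus genes, Dntt rose (1.03 ± 0.18) and Cd1d1 fell (-1.02 ± 0.19), with 1 and 1 adjusted over the list alone (list adjusted p = 0.927). Of 12 immediate early genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone), including Egr2 (-0.72 ± 0.10) and Jun (-0.60 ± 0.15), with a list adjusted p of 0.308, a median of 0.01 and a mean of -0.14. Syp (adjusted p of up to 0.0756), Cd1d1 (up to 0.0775) and Jun (up to 0.136) lost their calls without any 1 array other than tumour replicate 2, and Dntt (up to 0.0577) without control replicate 1 or 3 or tumour replicate 3. Without tumour replicate 2, 3 B and plasma cell genes and 1 MHC class II gene rose and 1 erythroid gene and 2 thymus genes fell; 1 erythroid gene fell without control replicate 1. The immediate early count was 1 without any 1 array other than tumour replicate 2.

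Central airway tissue in the tumour samples is a hypothesis that may account for part of the airway signal, and its test decided nothing. Of 14 cartilage genes, 2 rose and 0 fell: Comp (26.2 to 262.5, log2 2.56 ± 0.41, adjusted p = 0.0140) and Chad (411 to 1746, log2 2.07 ± 0.26, adjusted p = 0.00854). The 3 genes above an intensity of 100 in either group gave a shift of 1.86, which rests partly on that filter, since Comp met it through its tumour values alone and Cytl1 did not pass (adjusted p = 0.185). Over all 14 the median was 0.39, and Acan, Col2a1 and Matn1, core cartilage genes, stayed at mean intensities under 42 in both groups. Of 9 Schwann cell genes, S100b (2.24 ± 0.22) and Ncam1 (0.52 ± 0.12) rose and Mag (-1.10 ± 0.12) and Egr2 fell; the median over the 9 was 0.18. The shift over the 8 genes above an intensity of 100 in either group was 0.40, under the 0.5 set beforehand for both lists, and it too rests on the filter, which S100b and Ncam1 met through their tumour values alone. Both lists were written before their values were looked up, though Egr2 and Erbb3 had been seen as members of other lists. The levels of the core cartilage genes are too close to the floor to decide.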
